A study of Homo sapiens with 8 samples.

How the data were processed

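Total RNA from 8 samples was sequenced: 2 leiomyosarcoma cell lines, each transfected with a miR-10b-5p mimic or a control mimic at 20 nM, with 2 samples per group. Groups were taken from the sample titles and treatment fields. The authors' processing used FastQC and kallisto with genome build hg19, per the submitters' processing notes; versions, the transcript annotation and any selection of poly(A) RNA are not given in the sources used here. The deposited table lists a signal per transcript and library. From the values, this signal is kallisto's TPM multiplied by a factor per library that makes each column sum to about the library's assigned reads, since only 0.475% to 0.671% of values above 0 are whole numbers, and since low values of single-transcript genes become whole within 0.05 in 66.6% to 70.1% of cases once they are divided by a term that falls with transcript length. It is not a count of reads per transcript. No other scaling between libraries is stated.

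The table had 193845 lines. For 1689 transcripts the same values stood on several lines, 1 per gene identifier (19 with 2 symbols), and 1 line of each was kept. The 1958 lines left out held 0.221% to 0.277% of the column totals. Of the 191887 transcripts, 9542 (4.97%) had no gene symbol. They were kept under their annotated gene identifier or, without one, under the transcript identifier. They are thus in the totals and can be among the genes tested. Each column was rescaled to TPM. Transcripts were summed to 37217 genes by the symbols in the file, or by those identifiers where a symbol was missing. Genes with at least 1 TPM in 2 or more libraries were tested, 14965 in all.

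The comparisons, the tests, 32 gene lists, the alternatives marked as planned and the rule for the genes named were fixed before the data were examined. The plan had a branch for estimated counts and one for TPM, and the TPM branch was used because the values are not counts of reads. log2(TPM + 1) was fitted with limma 3.58.1 (R 4.3.3), with an intensity trend, as 4 group means over all 8 libraries, which share 1 estimate of the spread (4 residual degrees of freedom, 2.97 added by limma). The contrasts were mimic minus control in each line, their mean, their difference (SK-UT-1 minus SK-LMS-1) and SK-UT-1 minus SK-LMS-1 in control libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. Lists were tested with camera (limma), which asks whether a list's genes rank apart from all other genes, with a preset correlation of 0.01 and adjustment over the 32 lists within a contrast. An estimated correlation and fry were run beside it. Members are counted over all genes tested and adjusted over the list alone.

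Annotation came from GENCODE release 29 (GRCh38), which matched 168749 of the transcripts (87.9%). Coordinates are GRCh38 and were not converted from hg19. The 3′ UTR of a gene is the longest annotated among its protein-coding transcripts, and 13360 tested genes had one. Sites were 8-mers (ACAGGGTA), 7-mers (ACAGGGT or CAGGGTA) and 6-mers (CAGGGT). The difference of medians was tested by a two-sided permutation test with 100000 resamples across genes, and all 7-mers were ranked by the slope of the log2 change on their presence, with log UTR length and GC content as covariates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.

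Column totals of 17965252 to 21126365 set the depth. Because the deposited values weight reads by transcript length, reads per transcript were recovered from the values and the annotated lengths, at 98.1% to 98.6% of the column totals, and serve only to judge counting error and as an alternative (limma with voom weights). Tested on simulated counts with 100 genes changed per size among 14558, the fit recovered 22 of 100 genes changed by a log2 of 0.5 and 96 of 100 changed by 1 in SK-LMS-1, with 10 unchanged genes called, 21 and 91 with 9 in SK-UT-1, and 74 and 99 with 7 over both lines. A shifted list was called and 0 of 19 random lists were, under both correlations. The genes were simulated independently, so this cannot show how the preset correlation performs for lists whose members vary together. A planted site shift of −0.1 was estimated at −0.0996 with the site word at rank 1, and 0 of 40 simulations without a shift gave p under 0.05. The values for the sites were also drawn independently per gene. They cannot show how the permutation test or the ranking of words performs where genes vary together. Changes near a log2 of 0.5 were therefore often missed in a single line of the simulation of counts. It held far fewer changed genes than were called in the data, which makes the adjusted threshold stricter, so this rate need not hold for the data.

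Other settings fixed in advance were TMM-rescaled TPM (factors computed by an own implementation), no filter and a filter of 5 TPM, limma without the trend, pseudocounts of 0.1 and 0.5, only the 4 libraries compared, replicate number as a block, transcripts in place of genes, adjusted p under 0.01 or a change of at least 2-fold, other UTR and site choices, and leaving out each library. After seeing the data, voom on recovered reads, TPM without mitochondrial mRNA, centring on the median gene and leaving out genes with the words of the rises were added. The genes named are, per line, the 10 largest rises and 10 largest falls among called genes with at least 5 TPM in the higher group and no overlap between groups' libraries. Added to them are the 5 rises and 5 falls of smallest p called in both lines, the 5 largest of each direction for the difference between responses and between control lines, up to 4 called members per list and line with the largest change (up to 2 of highest level where none passed), and a fixed set of literature targets. Genes on chromosome Y, XIST, ribosomal and other pseudogenes and entries without a symbol were left out. No deposited column belongs to another sample. Some genes and 2 of the lists that these rules select are not reported here.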

Results

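RNA was sequenced from SK-LMS-1 and SK-UT-1, 2 human cell lines grown from leiomyosarcoma, a malignant tumour of smooth muscle. Each line received a synthetic mimic of miR-10b-5p, a microRNA encoded within a HOX gene cluster, or a control mimic, Negative Control #1, at 20 nM. The treatment field of the labels writes miR-10-5p where the sample titles write miR-10b-5p. The 8 libraries form 4 groups of 2, and the comparisons ask which transcripts change when the microRNA is added, in each line and in both. The column totals, which stand for the reads assigned per library, ran from 17965252 to 21126365, and 13099 to 13483 genes reached 1 TPM in a library. Levels are given as TPM, each gene's part of all transcripts of a library after division by transcript length, as mean ± SD over the n = 2 libraries of a group, and changes as log2 fold changes of TPM + 1 with their standard error, mimic minus control, which understates the change of genes of low level.

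Over log2 levels of the 14965 genes tested, the first principal component separated the lines (87.4% of the variance) and the second separated mimic from control libraries in both lines (5.33%). Libraries of a group correlated at r = 0.990 across genes in every group, and their spread exceeded counting error, with a median variance of 1.48 to 1.76 times the counting variance over genes with at least 20 reads. Mitochondrial mRNA made up 12.98% and 13.3% of TPM in the SK-LMS-1 control libraries against 13.9% and 14.7% with the mimic, and 8.24% and 7.31% against 9.02% and 9.22% in SK-UT-1. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

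In SK-LMS-1 the mimic was followed by the largest rise in MET, the receptor for hepatocyte growth factor (ENSG00000105976, chromosome 7, 116672390 to 116798386, in GRCh38 with GENCODE 29, as for all coordinates here), from 34.7 ± 0.417 to 204 ± 3.03 TPM, a log2 change of 2.52 ± 0.050 (limma adjusted p = 2.5e-06). PTPMT1, a phosphatase of the mitochondrial inner membrane, rose from 6.66 ± 0.978 to 34.9 ± 1.27 TPM (2.23 ± 0.11), and BANF1, a chromatin protein that bridges DNA after mitosis, from 64.9 ± 0.294 to 243 ± 12.8 TPM (1.89 ± 0.048). HMGA2, a chromatin architectural protein expressed in embryonic and many tumour cells (ENSG00000149948, chromosome 12, 65824131 to 65966295), rose from 146 ± 6.98 to 503 ± 3.43 TPM (1.78 ± 0.042, limma adjusted p = 3.6e-06). The other rises of the 10 largest included EPB41L1 (1.82), LRATD1 (1.77), PLPP3 (1.75) and SHROOM2 (1.73), and SERPINB4 (1.94), whose near-identical copy SERPINB3 leaves its level uncertain.

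SDC1, the heparan sulfate proteoglycan syndecan-1 (ENSG00000115884, chromosome 2, 20200797 to 20225433), fell most, from 70.0 ± 0.946 to 10.1 ± 0.143 TPM, a log2 change of −2.68 ± 0.064 (limma adjusted p = 3.6e-06). FCF1, which acts in ribosomal RNA processing, fell from 105 ± 1.13 to 16.6 ± 0.354 TPM (−2.59 ± 0.094), and SUMF1, which activates sulfatases, from 34.5 ± 1.00 to 6.25 ± 0.352 TPM (−2.29 ± 0.14). Falls of a similar size were measured for ST6GALNAC6, a sialyltransferase (−2.11), ARG2, the mitochondrial arginase (−1.96), IFIT2, an interferon-induced gene (−1.89), SKA1, a kinetochore protein (−1.88), and DOHH, which completes hypusine formation (−1.84). In all of these genes both mimic libraries lay on the same side of both control libraries, as the rule for naming them requires. Another of these falls, CHURC1-FNTB (−2.21), is a read-through annotation that shares its exons with CHURC1 and FNTB, and its call was lost when any 1 of the 4 SK-LMS-1 libraries was left out (adjusted p in parentheses): SK-LMS-1 control replicate 1 (0.129), SK-LMS-1 control replicate 2 (0.108), SK-LMS-1 mimic replicate 1 (0.116) and SK-LMS-1 mimic replicate 2 (0.118).

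Of the 14965 genes tested, 3670 changed in SK-LMS-1 at a limma adjusted p under 0.05, 1737 higher and 1933 lower, and 5505 had an unadjusted p under 0.05. Which direction held more genes depended on scaling, with 1895 higher and 1902 lower after TMM rescaling, 1926 and 1780 without mitochondrial mRNA, and 2000 and 1778 after centring on the median of all genes, the last 2 chosen after the result was seen. Changes were mostly small: 135 of the rises and 137 of the falls reached 2-fold. Leaving out 1 library lowered the count to 2089 without control replicate 1, 2095 without control replicate 2, 2269 without mimic replicate 1 and 2039 without mimic replicate 2, in fits where the lone library is assumed to vary like the other groups. With 2 libraries against 2, an exact two-sided permutation test of a single gene cannot go below 0.333, so each call rests on the spread that limma pools over genes and groups.

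In SK-UT-1, TAGLN, the smooth muscle actin-binding protein transgelin (ENSG00000149591, chromosome 11, 117199321 to 117204782), rose from 13.5 ± 1.47 to 83.0 ± 0.470 TPM, a log2 change of 2.53 ± 0.074 (limma adjusted p = 1.0e-05). PTPMT1 rose from 15.9 ± 1.71 to 77.1 ± 2.91 TPM (2.21 ± 0.11), EPB41L1, a membrane skeleton protein, from 7.03 ± 1.08 to 27.1 ± 1.84 TPM (1.81 ± 0.11), and HMGA2 from 53.8 ± 0.944 to 178 ± 0.380 TPM (1.70 ± 0.042). FXYD6, a regulator of the sodium pump, rose from 23.0 ± 2.90 to 85.9 ± 6.89 TPM (1.86 ± 0.20), and IGLON5, a neural adhesion protein of low level here, from 1.11 ± 0.619 to 5.33 ± 0.740 TPM (1.61 ± 0.21). TMEFF1 (1.69) and the read-through MSANTD3-TMEFF1 (1.74) overlap, so how much each contributed is uncertain. GNG8 was listed at 0 in 1 of its control libraries and at 6.67 and 10.98 TPM with the mimic. This rise rests on few recovered reads, 1 and 0 in control against 5 and 8 in mimic libraries. The GNG8 call was lost without SK-UT-1 mimic replicate 2.

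Large falls in SK-UT-1 included FCF1, from 49.9 ± 1.78 to 10.6 ± 1.65 TPM (−2.14 ± 0.094), and H3-3B, 1 of the genes of the replacement histone H3.3, from 831 ± 28.2 to 209.8 ± 9.10 TPM (−1.98 ± 0.053, limma adjusted p = 7.8e-06). RRBP1, a ribosome-binding protein of the endoplasmic reticulum, fell from 119.7 ± 8.55 to 30.6 ± 1.14 TPM (−1.93 ± 0.064), and P4HB, a protein disulfide isomerase, from 418 ± 23.7 to 111 ± 5.21 TPM (−1.90 ± 0.069). Among the others were CCNB3, a B-type cyclin (−1.92), CHST4, a sulfotransferase (−1.89), PCBD1 (−1.87) and LIX1L (−1.85). SMIM11A (2.69) and SMIM11B (−2.88) moved in opposite directions in SK-UT-1. They are near-identical copies whose reads can be assigned to either, and their summed level, a sum chosen after the values were seen, was 17.9 ± 1.34 TPM in control and 20.9 ± 0.767 TPM in mimic libraries.

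In this line 4591 genes changed, 3105 higher and 1486 lower, with 6240 at an unadjusted p under 0.05, and 189 of the rises and 117 of the falls reached 2-fold. The direction of the small changes depended on scaling: 67.6% of the calls were higher in the deposited scale, where the median log2 change of all genes was 0.080, and 46.0% (2034 higher, 2388 lower) after rescaling with TMM factors, which bring that median to 0. In settings chosen after the result was seen, the share was 71.15% without mitochondrial mRNA, 62.34% in recovered reads and 47.08% after centring on the median of all genes. Without mimic replicate 1 the count was 2718 and without mimic replicate 2 it was 2856.

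**Figure D1:**
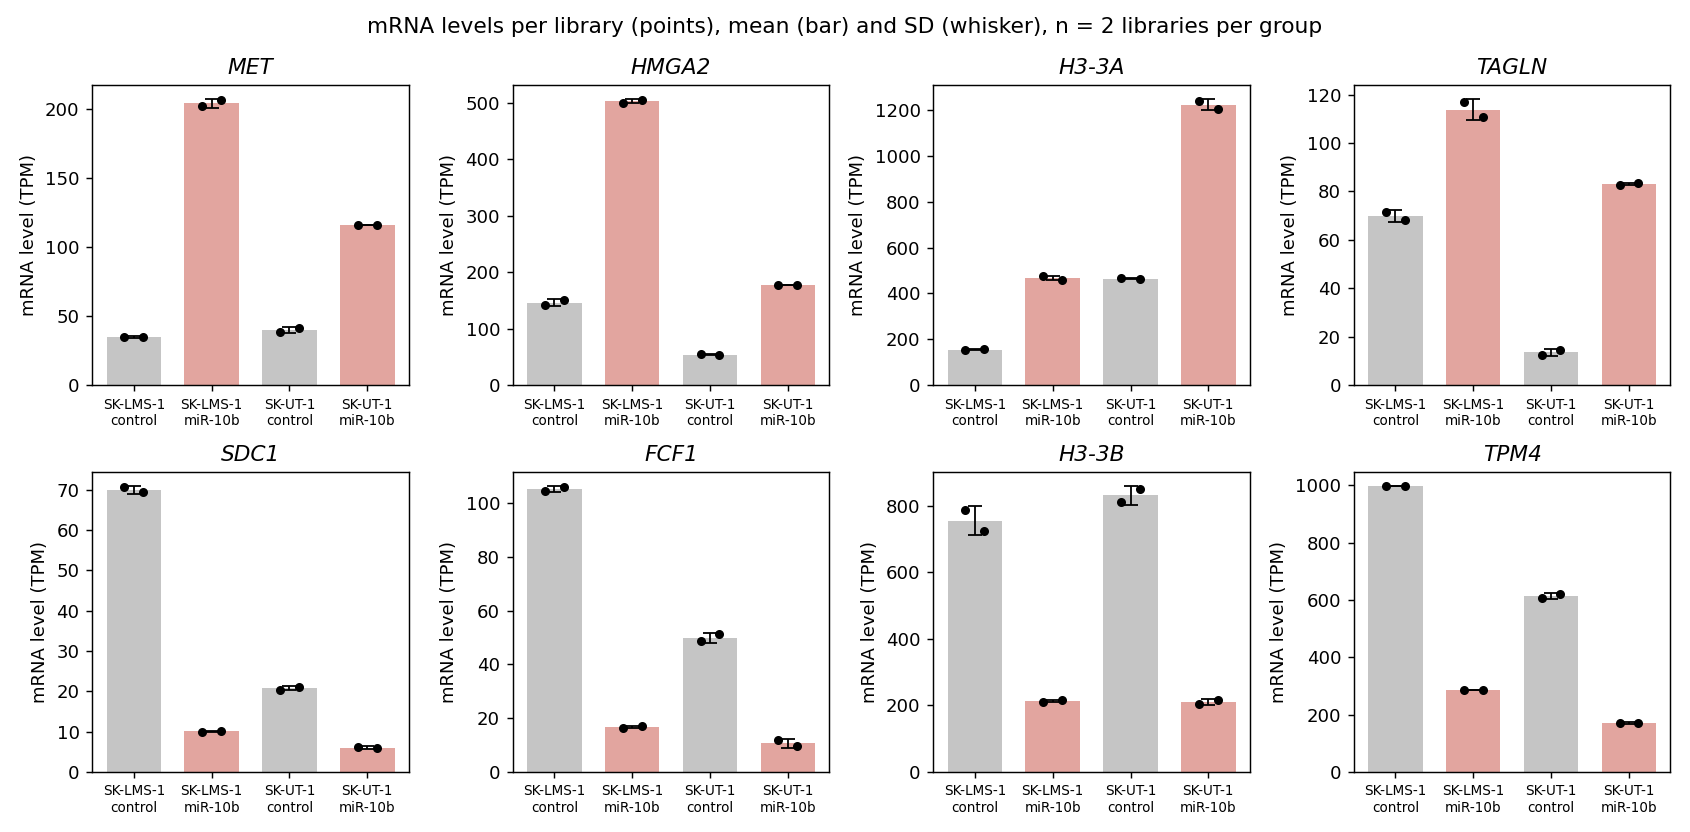
mRNA level in TPM of 8 genes in each library (points), with the group mean (bar) and SD (whisker) of n = 2 libraries, in control and miR-10b-5p mimic groups of SK-LMS-1 and SK-UT-1. MET stands at 34.7 against 204 TPM in SK-LMS-1, SDC1 at 70.0 against 10.1 TPM, and TAGLN at 13.5 against 83.0 TPM in SK-UT-1.

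Genes that changed the same way in both lines included both H3.3 genes, in opposite directions. H3-3A rose from 154 ± 3.05 to 467 ± 10.3 TPM in SK-LMS-1 and from 464 ± 1.65 to 1223 ± 24.2 TPM in SK-UT-1 (log2 1.59 and 1.40), while H3-3B fell from 755 ± 44.5 to 212 ± 3.70 TPM in SK-LMS-1 (−1.83) and by 1.98 in SK-UT-1. Both genes have processed copies in the genome that could take some of their reads. TPM4, a non-muscle tropomyosin, fell from 998 ± 0.722 to 286 ± 0.00182 TPM in SK-LMS-1 and from 614 ± 9.77 to 170.3 ± 2.004 TPM in SK-UT-1, with a mean log2 change over the lines of −1.82 ± 0.021 (limma adjusted p = 1.1e-07). MET (2.02 ± 0.035), HMGA2 (1.74 ± 0.029), BANF1 (1.60 ± 0.034) and CYRIB, a binding partner of Rac1 (1.42 ± 0.031), rose over both lines, and SDC1 (−2.16 ± 0.045), PCBD1 (−1.77 ± 0.035) and CMPK1, the UMP-CMP kinase (−1.35 ± 0.033), fell.

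Across both lines 5539 genes changed on average, 3293 higher and 2246 lower, or 2688 higher and 2866 lower after TMM rescaling. Calls of the separate lines overlapped: 1057 genes rose and 805 fell in both, where independent lists of these sizes would share 360.4 and 191.9, and 140 were called in opposite directions against 573.5. Over all genes tested the changes in the lines had Pearson's r = 0.409 and a rank correlation of 0.433, a relation across genes, which are not independent replicates. The lines share no control library.

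Messenger RNAs with a match to the miR-10b-5p seed in their 3′ UTR were lower than other mRNAs after the mimic in both lines. The seed, bases 2 to 8 of the microRNA, pairs with ACAGGGT, and ACAGGGTA is the 8-mer site. SDC1 and FCF1 each hold an 8-mer in the annotated 3′ UTR (GRCh38 chromosome 2, 20202009 to 20202016, in the context CATGTGTGCAACAGGGTATGGACTATCT, and chromosome 14, 74735316 to 74735323, in AGCTAGAGAAACAGGGTATTTACAATGC), and ARG2 and SKA1 hold 1 each. H3-3B holds a 7-mer (chromosome 17, 75778280 to 75778286), as does TPM4 (chromosome 19, 16101608 to 16101614), while MET has only a 6-mer match (chromosome 7, 116798093 to 116798098). Among the 10 genes of largest fall 8 of 10 held a 7-mer or 8-mer in SK-LMS-1 and 7 of 10 in SK-UT-1, against 1 of 10 and 0 of the 9 largest rises with an annotated 3′ UTR.

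The 2544 genes with a 7-mer or 8-mer, of 13360 with an annotated 3′ UTR, had a median log2 change of −0.076 in SK-LMS-1 against 0.003 in the 8431 genes without even the 6-mer CAGGGT, a difference of −0.078 (permutation test across genes, two-sided, p = 1e-05, the smallest that 100000 resamples can give). In SK-UT-1 the medians were 0.022 and 0.086, a difference of −0.064 (same permutation test, p = 1e-05). The share of genes that fell was larger with a longer match: 24.7% of genes with an 8-mer, 22.4% with a 7-mer, 13.5% with a 6-mer and 11.4% without a match in SK-LMS-1, and 21.5%, 16.9%, 9.85% and 8.82% in SK-UT-1. The share that rose was 8.54%, 9.20%, 13.2% and 13.1% in SK-LMS-1 and 11.7%, 17.5%, 26.2% and 22.4% in SK-UT-1, so there 6-mer genes rose more often than genes without a match, and 7-mer genes rose (391) about as often as they fell (377). These counts are in the deposited scale, where the median log2 change of all SK-UT-1 genes was 0.080. Genes without a match rose (1891) more often than they fell (744) in that line. Shares by match were not counted after TMM rescaling. Of all possible 7-mers, ACAGGGT had the most negative slope of log2 change on its presence in both lines, with UTR length and GC content in the fit (t = −15.1 and −16.1, slopes of −0.13 ± 0.009 and −0.15 ± 0.009), and CAGGGTA, the other 7-mer of the site, ranked 2 in both. GGATTAC, which is no seed match, ranked 7 in SK-LMS-1 and 8 in SK-UT-1 (t = −6.68 and −6.56). These lie below the lowest t of 100 shufflings of the fold changes over genes (−5.21 and −5.11). Genes with a 6-mer match alone differed from genes without a match by 0.002 and 0.034, the opposite sign (permutation test, p = 0.786 and 6e-05).

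**Figure D2:**
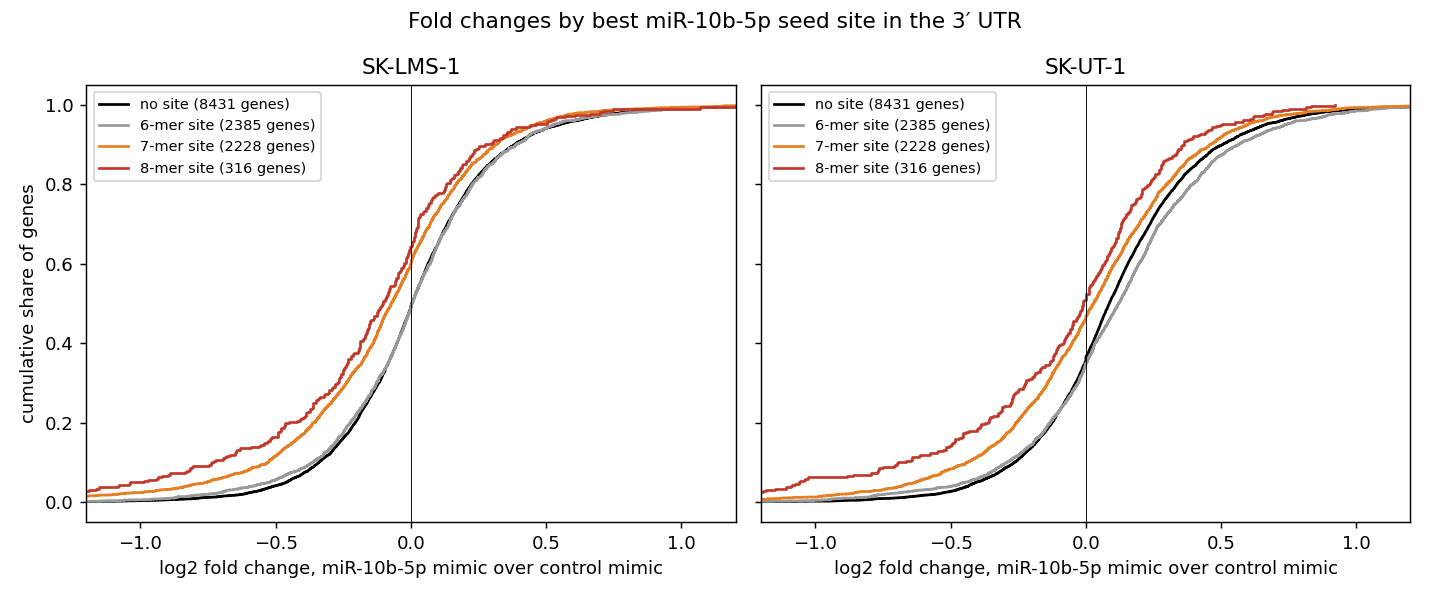
Cumulative share of genes (vertical axis) against the log2 fold change of mimic over control (horizontal axis), by the best miR-10b-5p seed match in the 3′ UTR (none, 6-mer, 7-mer, 8-mer), in SK-LMS-1 (left) and SK-UT-1 (right). The 316 genes with an 8-mer lie furthest to the left, with medians of −0.105 and −0.011, against 0.003 and 0.086 for genes without a match.

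Of 57 genes described in other cells as targets of miR-10b-5p or of its same-seed sibling miR-10a-5p, 50 were measured. In SK-LMS-1 17 of them fell, 3 rose and 30 did not pass the test (3 higher and 19 lower adjusted over the list alone), and in SK-UT-1 17 fell, 7 rose and 26 did not pass (7 higher and 19 lower adjusted over the list alone). The falls numbered 17 in SK-LMS-1 and 23 in SK-UT-1 after TMM rescaling, and 13 and 14 with only the 4 libraries of each line. In recovered reads, a setting chosen after the result was seen, they numbered 25 and 22. SDC1, USP46, a deubiquitinase (−1.30 in SK-LMS-1 and −1.43 in SK-UT-1), ZMYND11, a chromatin reader (−1.22 in SK-LMS-1 and −1.12 in SK-UT-1), and KLF4, a transcription factor (−0.84 in SK-LMS-1 and −0.98 in SK-UT-1), fell in both lines, as did MAPRE1, a microtubule plus-end protein (−0.55 in SK-LMS-1 and −0.31 in SK-UT-1). E2F7, an atypical E2F repressor, fell in SK-LMS-1 (−1.26, against −0.18, limma adjusted p = 0.098, in SK-UT-1, where it passed in recovered reads at −0.26, 7.5e-05). TFAP2C, an AP-2 factor (−1.18), and NF1, a negative regulator of RAS (−0.66), fell in SK-UT-1, with 0.15 and 0.037 in SK-LMS-1, neither past the test. SRSF1 rose in SK-UT-1 (0.31).

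HOXD10, a described target of miR-10b, did not pass the test in TPM in either line, at 14.4 ± 0.0716 to 11.02 ± 1.87 TPM in SK-LMS-1 (−0.36 ± 0.20, limma adjusted p = 0.235) and 1.11 ± 0.1998 to 1.38 ± 0.625 TPM in SK-UT-1 (0.15 ± 0.20, limma adjusted p = 0.612). In recovered reads it passed in SK-LMS-1 (−0.40, limma adjusted p = 0.03). Its 3′ UTR holds a 7-mer (chromosome 2, 176119507 to 176119513). Also short of the test in TPM in both lines were BCL2L11 (−0.34 and −0.010), USF2 (0.16 and −0.087), BTRC (−0.081 and −0.14) and HOXB3 (0.018 and −0.21). In recovered reads BTRC was lower in both lines (−0.80, limma adjusted p = 5.3e-07, and −0.38, 1.0e-04). BCL2L11 passed there in SK-LMS-1 (−0.78, limma adjusted p = 1.4e-05), as did USF2 (0.13, 0.038), and HOXB3 in SK-UT-1 (−0.41, 1.3e-04). CDKN1A, the p21 gene, rose in both lines (0.53 and 0.88), but its SK-LMS-1 call was lost (adjusted p in parentheses) without SK-LMS-1 control replicate 2 (0.054) or SK-LMS-1 mimic replicate 1 (0.057). TIAM1, a Rac activator, fell in both lines (−0.36 and −0.51), and in SK-LMS-1 that call was lost without SK-LMS-1 control replicate 1 (0.137), SK-LMS-1 control replicate 2 (0.115) or SK-LMS-1 mimic replicate 2 (0.16). TRA2B fell in SK-LMS-1 by 0.20, a call lost without SK-LMS-1 control replicate 1 (0.089), SK-LMS-1 control replicate 2 (0.145) or SK-LMS-1 mimic replicate 1 (0.155). As a list, the targets were lower than other genes in SK-LMS-1 (camera adjusted p = 0.021, adjusted p = 0.573 with an estimated correlation) and in SK-UT-1 (camera adjusted p = 7.3e-05, adjusted p = 0.303 with an estimated correlation), and the SK-LMS-1 call was lost without SK-LMS-1 mimic replicate 1 (0.083).

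Of 51 measured genes of G2/M and mitosis in SK-LMS-1, 46 fell and 0 rose (0 higher and 48 lower adjusted over the list alone), with a median log2 change of −0.42. Among them were ANLN, needed for cytokinesis (−1.53), CDC25C, a CDK1 phosphatase (−0.90), CKS1B (−0.70) and UBE2C, the ubiquitin-conjugating enzyme of mitotic exit (−0.65). For mitosis genes camera adjusted p = 3.6e-22, or adjusted p = 0.25 with an estimated correlation. Of 50 genes of G1/S and DNA replication, 24 fell and 2 rose (3 higher and 30 lower adjusted over the list alone). LIG1, the replicative DNA ligase (−1.08), CDC6 (−0.90) and MCM10 (−0.71) fell. For G1/S genes camera adjusted p = 6.3e-05, or adjusted p = 0.573 with an estimated correlation.

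Glycolysis and hypoxia genes were higher in SK-LMS-1, where 17 of 34 rose and 3 fell (20 higher and 3 lower adjusted over the list alone). SLC2A3, a glucose transporter (1.45), ANGPTL4 (1.30), NDRG1 (0.84) and ADM, adrenomedullin (0.81), rose. For this list camera adjusted p = 1.1e-05, or adjusted p = 0.573 with an estimated correlation. In the RAS-MAPK list 10 of 31 rose and 2 fell (10 higher and 2 lower adjusted over the list alone). MET was among its rises and RPS6KA1, the kinase RSK1 (−1.22), among its falls. For the RAS-MAPK list camera adjusted p = 0.019, or adjusted p = 0.573 with an estimated correlation.

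Interferon-stimulated genes were lower in SK-LMS-1, where 14 of 49 fell and 3 rose (3 higher and 15 lower adjusted over the list alone). Falls were measured for IFIT2, OASL (−1.34), IFIT3 (−1.28) and IFIT1 (−1.19). For interferon-stimulated genes camera adjusted p = 0.022, or adjusted p = 0.573 with an estimated correlation. The call was lost without SK-LMS-1 mimic replicate 1 (0.057). Nuclear genes of oxidative phosphorylation were also lower, with 11 of 47 falls and 3 rises (3 higher and 11 lower adjusted over the list alone), in libraries whose mitochondrial mRNA share was higher. NDUFA1 (−0.75) and COX4I1 (−0.44) fell. For oxidative phosphorylation camera adjusted p = 0.036, or adjusted p = 0.573 with an estimated correlation. That call was lost without SK-LMS-1 control replicate 1 (0.092), without SK-LMS-1 mimic replicate 2 (0.119) and with each library centred on its median (0.124).

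The same cell cycle lists went apart in SK-UT-1. Of 51 mitosis genes 21 fell and 6 rose (7 higher and 21 lower adjusted over the list alone), and ANLN (−1.34), HMMR (−0.65), BUB1 (−0.61) and CENPF (−0.52) were among the falls. For mitosis genes camera adjusted p = 5.8e-05, or adjusted p = 0.351 with an estimated correlation. Of the 50 G1/S genes 21 rose and 2 fell (23 higher and 3 lower adjusted over the list alone), and E2F2 (1.29), GINS2 (0.75), MCM6 (0.74) and TK1 (0.73) were among the rises. For G1/S genes camera adjusted p = 0.0038, or adjusted p = 0.575 with an estimated correlation. None of 15 replication-dependent histone genes rose and 5 fell (0 higher and 5 lower adjusted over the list alone), with H2AC6 (−0.98) and H1-2 (−0.88) among them. For histone genes camera adjusted p = 2.7e-04, or adjusted p = 0.171 with an estimated correlation. These transcripts mostly lack poly(A) tails, so their level also depends on the RNA selection, which the labels do not state.

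Smooth muscle contractile genes were higher in SK-UT-1, where 18 of 28 rose and 3 fell (19 higher and 4 lower adjusted over the list alone). TAGLN and ACTA2, the smooth muscle actin (1.41), rose, while TPM4 and DES, the intermediate filament desmin (−1.61), fell. For smooth muscle genes camera adjusted p = 0.0015, or adjusted p = 0.171 with an estimated correlation. In SK-LMS-1 7 rose and 5 fell (7 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.626), with TAGLN at 0.70 and ACTA2 at 0.88. In the Wnt list 17 of 35 rose and 0 fell in SK-UT-1, or 14 and 3 after TMM rescaling (18 higher and 3 lower adjusted over the list alone). VANGL2, a planar polarity protein (1.18), and DKK3 (0.89) rose. For Wnt genes camera adjusted p = 0.016, or adjusted p = 0.351 with an estimated correlation.

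NF-kB and inflammatory cytokine genes were lower in SK-UT-1, where 13 of 31 fell and 0 rose (0 higher and 13 lower adjusted over the list alone). The chemokines CXCL3 (−1.66), CXCL8 (−1.201) and CXCL1 (−1.14) and TNFAIP2 (−1.43) fell. For NF-kB genes camera adjusted p = 4.2e-05, or adjusted p = 0.171 with an estimated correlation. Of 27 immediate early genes 13 fell and 2 rose (3 higher and 14 lower adjusted over the list alone), with KLF4, DUSP5 (−0.89), IER3 (−0.66) and FOS (−0.65) among the falls. For immediate early genes camera adjusted p = 2.1e-05, or adjusted p = 0.191 with an estimated correlation. In the unfolded protein and ATF4 response list 14 of 35 fell and 8 rose (9 higher and 15 lower adjusted over the list alone). EDEM1 (−1.18) and DDIT3, the CHOP gene (−0.93), fell, and PDIA4 (0.84) and SEL1L (0.66) rose. For the unfolded protein list camera adjusted p = 0.0066, or adjusted p = 0.528 with an estimated correlation.

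Among genes of protein synthesis, 28 of 62 cytosolic ribosomal protein genes fell and 2 rose in SK-UT-1, or 49 and 0 after TMM rescaling (3 higher and 31 lower adjusted over the list alone). RPL3 (−0.53) and RPL13A (−0.39) were among the falls, though many of these genes have pseudogene copies, which leaves single members uncertain. For ribosomal protein genes camera adjusted p = 3.2e-12, or adjusted p = 0.268 with an estimated correlation. Of 47 oxidative phosphorylation genes 13 fell and 5 rose, or 24 and 0 after TMM rescaling (5 higher and 13 lower adjusted over the list alone), with NDUFA1 (−0.85) and COX4I1 (−0.51) among the falls. For oxidative phosphorylation genes camera adjusted p = 0.0025, or adjusted p = 0.303 with an estimated correlation. The MYC and ribosome biogenesis list had 9 of 37 members lower and 3 higher (3 higher and 9 lower adjusted over the list alone), with RRP9 (−0.48) and DKC1, dyskerin (−0.46), among the falls. For the MYC list camera adjusted p = 0.0086, or adjusted p = 0.575 with an estimated correlation. This call was lost without SK-UT-1 control replicate 2 (0.094).

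**Figure D3:**
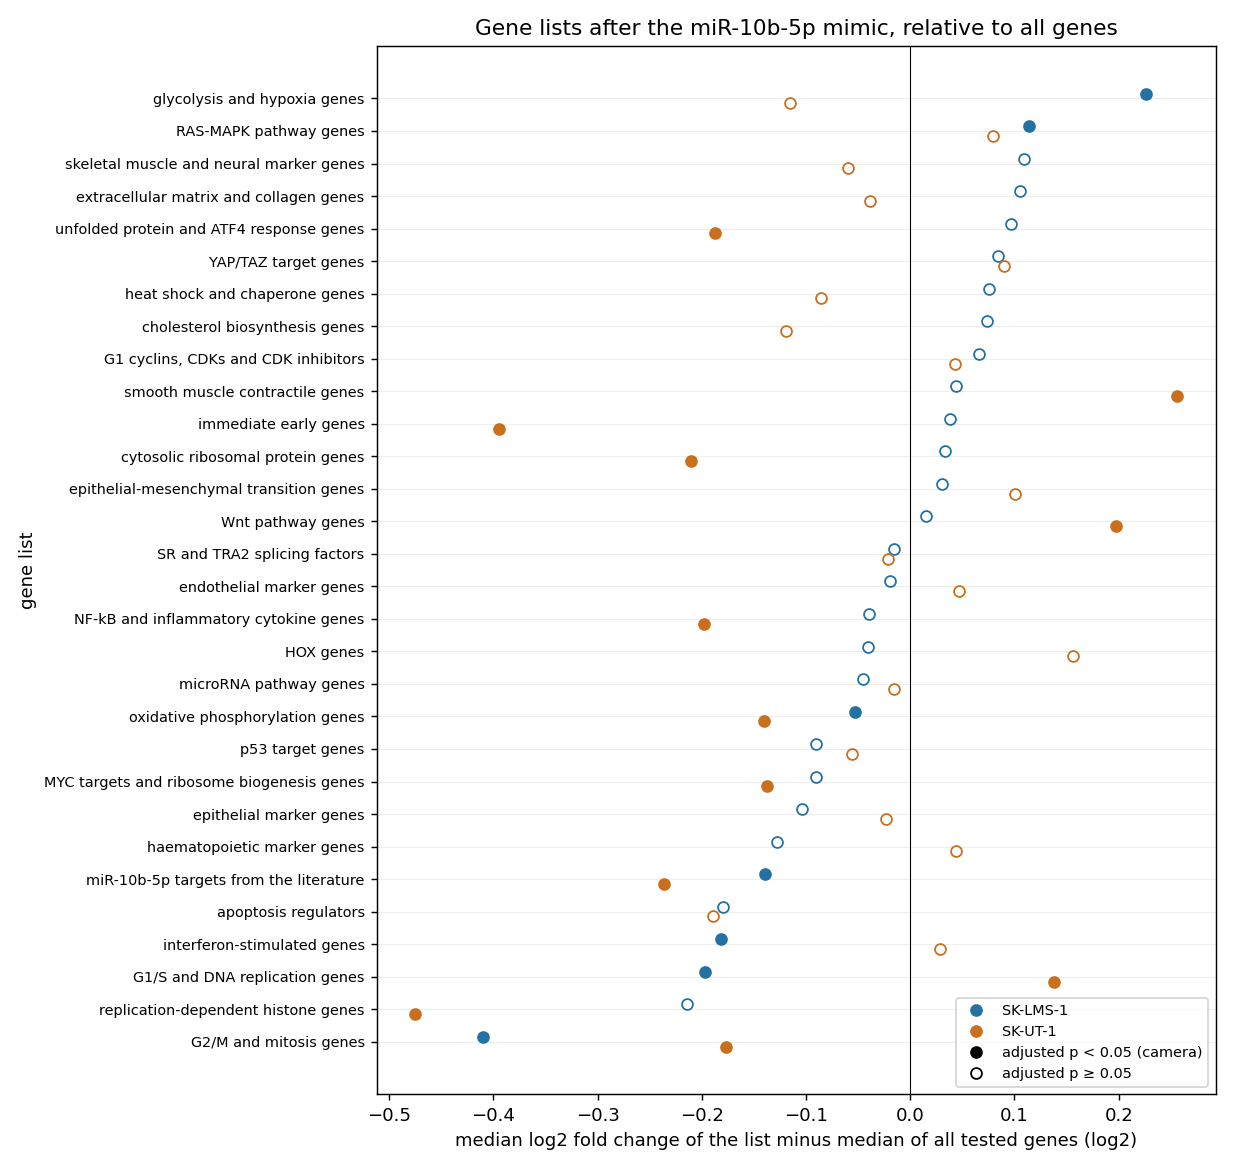
Median log2 fold change of each of 30 gene lists minus the median of all genes (horizontal axis) in SK-LMS-1 (blue) and SK-UT-1 (orange), filled where camera's adjusted p was under 0.05. Mitosis genes lie at −0.41 and −0.18, below other genes in both lines, and glycolysis and hypoxia genes at 0.23 in SK-LMS-1 and −0.12 in SK-UT-1.

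Lists called in SK-UT-1 alone had these counts in SK-LMS-1. TNFAIP2 (−1.46) and CXCL8 (−1.29) were 2 of 6 falls in the NF-kB list, with 1 rise (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.28). Of the immediate early genes 6 rose and 6 fell (6 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.859), with KLF4 at −0.84 and DUSP4 at 0.77. Ribosomal protein genes had 6 rises and 6 falls, 7 and 6 after TMM rescaling and 11 and 12 in recovered reads (6 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.626). In the MYC list 6 rose and 10 fell (6 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.127), with DKC1 at −0.82 and RRS1 at 0.75. In the unfolded protein list 12 rose and 11 fell (15 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.713), with PDIA4 at 1.65 and EDEM1 at −1.16. WNT7B (0.88) was 1 of 4 rises in the Wnt list, with 0 falls (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.592). Of the histone genes 0 rose and 1 fell, H2BC12 (−0.20), a fall lost in recovered reads, after TMM rescaling and without SK-LMS-1 control replicate 1 (0.057), SK-LMS-1 control replicate 2 (0.202), SK-LMS-1 mimic replicate 1 (0.181) or SK-LMS-1 mimic replicate 2 (0.093) (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.28).

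Lists called in SK-LMS-1 alone had these counts in SK-UT-1. SP110 (0.58) was 1 of 10 rises of interferon-stimulated genes, with 3 falls as deposited but 3 rises and 8 falls after TMM rescaling (10 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.888). The RAS-MAPK list had 13 rises, MET (1.52) among them, and 3 falls (14 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.162). NDRG1 (−0.71) and ENO2 (−0.68) were 2 of 8 falls in the glycolysis and hypoxia list, with 6 rises, or 2 rises and 13 falls after TMM rescaling and 7 of each without mitochondrial mRNA (7 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.069). This list was called, as lower, without SK-UT-1 control replicate 1 (0.037) or SK-UT-1 mimic replicate 1 (0.047).

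The lists that follow were called in neither line. Of 24 measured G1 cyclins, CDKs and CDK inhibitors, 8 rose and 4 fell in SK-LMS-1 (8 higher and 6 lower adjusted over the list alone). In SK-UT-1 10 rose and 3 fell (11 higher and 3 lower adjusted over the list alone). CCND3, cyclin D3 (1.66 and 1.02), and E2F5 (0.95 and 1.41) rose in both lines, and CDK6 fell in SK-LMS-1 (−1.03). For G1 cyclins camera adjusted p = 0.497 in SK-LMS-1 and 0.308 in SK-UT-1, or adjusted p = 0.791 and 0.599 with an estimated correlation. Of 29 measured p53 target genes, 4 rose and 6 fell in SK-LMS-1 (4 higher and 7 lower adjusted over the list alone). In SK-UT-1 4 rose and 5 fell, or 3 and 8 after TMM rescaling (4 higher and 5 lower adjusted over the list alone). MDM2, the ubiquitin ligase of p53, whose longest annotated 3′ UTR of 10837 bases holds 5 7-mer matches, fell in both lines (−1.56 and −1.36), and SESN1 rose in SK-LMS-1 (0.78). For p53 target genes camera adjusted p = 0.28 in SK-LMS-1 and 0.36 in SK-UT-1, or adjusted p = 0.573 and 0.575 with an estimated correlation. Of 30 measured apoptosis regulators, 7 rose and 9 fell in SK-LMS-1 (8 higher and 13 lower adjusted over the list alone). In SK-UT-1 6 rose and 7 fell (6 higher and 9 lower adjusted over the list alone). MCL1, an anti-apoptotic BCL2 family member, rose in both (1.13 and 0.83), and APAF1 fell in SK-LMS-1 (−0.67). For apoptosis regulators camera adjusted p = 0.47 in SK-LMS-1 and 0.069 in SK-UT-1, or adjusted p = 0.751 and 0.351 with an estimated correlation.

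Matrix and adhesion genes were likewise mixed. Of 41 measured extracellular matrix and collagen genes, 8 rose and 9 fell in SK-LMS-1, or 19 and 15 in recovered reads (9 higher and 11 lower adjusted over the list alone). In SK-UT-1 9 rose and 9 fell, or 7 and 10 after TMM rescaling (9 higher and 9 lower adjusted over the list alone). COL5A2 fell in both lines (−0.94 and −1.19) and COL5A1 in SK-LMS-1 (−1.34). For matrix genes camera adjusted p = 0.831 in SK-LMS-1 and 0.401 in SK-UT-1, or adjusted p = 0.883 and 0.599 with an estimated correlation. Of 25 measured epithelial-mesenchymal transition genes, 3 rose and 5 fell in SK-LMS-1, or 6 and 4 after TMM rescaling (7 higher and 8 lower adjusted over the list alone). In SK-UT-1 4 rose and 7 fell (5 higher and 7 lower adjusted over the list alone). CD44 fell in both lines (−0.36 and −0.98), with a limma adjusted p of 4.7e-05 in SK-UT-1. For epithelial-mesenchymal genes camera adjusted p = 0.831 in SK-LMS-1 and 0.414 in SK-UT-1, or adjusted p = 0.883 and 0.575 with an estimated correlation. Of 24 measured YAP/TAZ target genes, 9 rose and 4 fell in SK-LMS-1 (11 higher and 8 lower adjusted over the list alone). In SK-UT-1 8 rose and 4 fell (9 higher and 4 lower adjusted over the list alone). WWTR1, which encodes TAZ itself (1.54 and 1.11), and PTPN14 (1.09 and 1.06) rose in both, and ANKRD1 fell in SK-LMS-1 (−1.63). For YAP/TAZ targets camera adjusted p = 0.361 in SK-LMS-1 and 0.902 in SK-UT-1, or adjusted p = 0.751 and 0.942 with an estimated correlation.

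The remaining lists cover development, metabolism and RNA. Of 35 measured HOX genes, 2 rose and 3 fell in SK-LMS-1, or 3 and 3 after TMM rescaling (2 higher and 1 lower adjusted over the list alone). In SK-UT-1 7 rose and 2 fell (7 higher and 2 lower adjusted over the list alone). HOXA13 (0.61) rose in SK-LMS-1 and HOXC13 (0.80) in SK-UT-1. For HOX genes camera adjusted p = 0.833 in SK-LMS-1 and 0.36 in SK-UT-1, or adjusted p = 0.883 and 0.575 with an estimated correlation. Of 25 measured cholesterol biosynthesis genes, 6 rose and 2 fell in SK-LMS-1 (9 higher and 2 lower adjusted over the list alone). In SK-UT-1 5 rose and 5 fell, or 4 and 8 after TMM rescaling and 7 and 5 without mitochondrial mRNA (7 higher and 6 lower adjusted over the list alone). MSMO1 rose in SK-LMS-1 (0.43). For cholesterol genes camera adjusted p = 0.175 in SK-LMS-1 and 0.36 in SK-UT-1, or adjusted p = 0.751 and 0.768 with an estimated correlation. Of 22 measured heat shock and chaperone genes, 5 rose and 2 fell in SK-LMS-1 (5 higher and 2 lower adjusted over the list alone). In SK-UT-1 3 rose and 5 fell (4 higher and 5 lower adjusted over the list alone). HSP90AA1 (1.19 and 0.44) rose and HSPA4L (−0.97 and −1.06) and CHORDC1 (−0.95 and −0.95) fell in both. For heat shock genes camera adjusted p = 0.604 in SK-LMS-1 and 0.309 in SK-UT-1, or adjusted p = 0.883 and 0.768 with an estimated correlation. Of 27 measured microRNA pathway genes, 3 rose and 2 fell in SK-LMS-1, or 6 and 10 in recovered reads (3 higher and 2 lower adjusted over the list alone). In SK-UT-1 5 rose and 2 fell (5 higher and 1 lower adjusted over the list alone). CNOT7, a deadenylase subunit, rose in both (0.59 and 0.82). For microRNA pathway genes camera adjusted p = 0.756 in SK-LMS-1 and 0.651 in SK-UT-1, or adjusted p = 0.883 and 0.791 with an estimated correlation. Of 25 measured SR and TRA2 splicing factors, 3 rose and 3 fell in SK-LMS-1 (4 higher and 3 lower adjusted over the list alone). In SK-UT-1 7 rose and 0 fell, or 3 and 1 after TMM rescaling (7 higher and 0 lower adjusted over the list alone). CLK3 rose (0.59) and SRSF7 fell (−0.33) in SK-LMS-1. For splicing factors camera adjusted p = 0.833 in SK-LMS-1 and 0.36 in SK-UT-1, or adjusted p = 0.883 and 0.599 with an estimated correlation.

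Most markers of other cell types did not change, apart from skeletal muscle and neural markers in SK-LMS-1. Of 13 measured epithelial marker genes 3 fell in SK-LMS-1 and 1 rose and 2 fell in SK-UT-1 (the same counts adjusted over the list alone), KRT7 falling in both (−0.52 and −0.66). In SK-UT-1 the KRT7 fall rests on few recovered reads, 12 and 16 in control against 8 and 5 in mimic libraries. For epithelial markers camera adjusted p = 0.28 in SK-LMS-1 and 0.45 in SK-UT-1, or adjusted p = 0.573 and 0.599 with an estimated correlation. None of 7 haematopoietic marker genes changed in SK-LMS-1, and in SK-UT-1 CORO1A rose (0.88) and CD68 fell (−0.91) (the same counts adjusted over the list alone). For haematopoietic markers camera adjusted p = 0.606 in SK-LMS-1 and 0.513 in SK-UT-1, or adjusted p = 0.751 and 0.601 with an estimated correlation. Of 6 endothelial marker genes only EMCN changed, a rise in SK-UT-1 (0.65), while ENG was at 0.28 in SK-LMS-1, past the test in recovered reads but not in TPM (the same counts adjusted over the list alone). For endothelial markers camera adjusted p = 0.811 in SK-LMS-1 and 0.769 in SK-UT-1, or adjusted p = 0.883 and 0.791 with an estimated correlation. Of 8 skeletal muscle and neural marker genes 3 rose and 2 fell in SK-LMS-1 and 1 fell in SK-UT-1 (the same counts adjusted over the list alone). TUBB3 rose in SK-LMS-1 (0.69) and fell in SK-UT-1 (−0.37), and NEFL fell in SK-LMS-1 (−0.77). For skeletal muscle and neural markers camera adjusted p = 0.592 in SK-LMS-1 and 0.36 in SK-UT-1, or adjusted p = 0.751 and 0.575 with an estimated correlation.

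For some lists the median, the mean and camera's direction differ in sign, given here in that order. Camera's direction is relative to all other genes, while the median and mean are relative to 0. The median log2 change of all genes was −0.006 in SK-LMS-1 and 0.080 in SK-UT-1. In SK-LMS-1 these were immediate early genes (0.032, −0.032, down), the unfolded protein list (0.091, −0.030, up) and endothelial markers (−0.026, 0.039, up). In SK-UT-1 they were p53 targets (0.024, 0.0012, down), interferon-stimulated genes (0.11, 0.069, down), matrix genes (0.041, −0.020, down) and epithelial-mesenchymal genes (0.18, −0.0075, down). The same held there for epithelial (0.056, −0.052, down), haematopoietic (0.12, 0.032, down) and skeletal muscle and neural markers (0.020, −0.047, down). Camera with its preset correlation called 7 of the 32 lists in SK-LMS-1 and 12 in SK-UT-1. None was called in either line with an estimated correlation in camera, where 1 list in SK-LMS-1 and 5 in SK-UT-1 had an unadjusted p under 0.05. fry, which asks whether a list's genes move one way on balance, called 12 and 17.

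The response itself differed between the lines for 1315 genes at a limma adjusted p under 0.05, with 4047 at an unadjusted p under 0.05. TAGLN rose by 1.84 ± 0.10 more in SK-UT-1 than in SK-LMS-1 (limma adjusted p = 0.0012). IFIT2 fell in SK-LMS-1 (−1.89) and was at −0.24 in SK-UT-1, past the test there in recovered reads but not in TPM, a difference of 1.65 ± 0.12. RGS2, a brake on G protein signalling, rose from 8.16 ± 0.425 to 21.4 ± 0.575 TPM in SK-LMS-1 and fell from 4.08 ± 0.514 to 2.11 ± 0.338 TPM in SK-UT-1 (difference −2.001 ± 0.17). Other large differences concerned genes with almost no transcript in 1 of the lines. LRATD1 (−1.76) and SERPINB4 (−1.94) were under 0.1 TPM in each SK-UT-1 library, and FXYD6 (1.89) and MYBPH (−1.88) under 0.6 TPM in each SK-LMS-1 library. Differences are relative to a median over all genes of 0.094 in the deposited scale, which TMM rescaling moves to −0.008. With it the calls move from 898 higher and 417 lower to 472 and 791.

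Responses of whole lists also differed. LIG1 (0.92) and TK1 (0.34) belong to the G1/S list, which had 24 higher and 0 lower responses in SK-UT-1 of 50 members (40 higher and 0 lower adjusted over the list alone). For these G1/S genes camera adjusted p = 3.3e-13, or adjusted p = 0.123 with an estimated correlation. Mitosis genes had 26 higher and 0 lower responses of 51 (36 higher and 1 lower adjusted over the list alone). For the mitosis genes camera adjusted p = 1.9e-10, or adjusted p = 0.123 with an estimated correlation. Interferon-stimulated genes, IFIT2 among them, had 8 higher and 0 lower responses of 49 (10 higher and 2 lower adjusted over the list alone). For the interferon-stimulated genes camera adjusted p = 0.013, or adjusted p = 0.306 with an estimated correlation. That call was lost without SK-UT-1 control replicate 2 (0.114) or SK-UT-1 mimic replicate 1 (0.07). Smooth muscle genes, TAGLN among them, had 13 higher and 1 lower responses of 28 (13 higher and 1 lower adjusted over the list alone). For the smooth muscle genes camera adjusted p = 4.6e-04, or adjusted p = 0.123 with an estimated correlation. Glycolysis and hypoxia genes, NDRG1 (−1.55) among them, had 1 higher and 11 lower responses of 34 (1 higher and 19 lower adjusted over the list alone). For glycolysis and hypoxia genes camera adjusted p = 5.6e-14, or adjusted p = 0.123 with an estimated correlation. NF-kB genes had 0 higher and 8 lower responses of 31 (0 higher and 8 lower adjusted over the list alone). For the NF-kB genes camera adjusted p = 9.4e-04, or adjusted p = 0.123 with an estimated correlation. Immediate early genes had 0 higher and 7 lower responses of 27 (0 higher and 7 lower adjusted over the list alone). For the immediate early genes camera adjusted p = 3.2e-06, or adjusted p = 0.123 with an estimated correlation.

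Ribosomal protein genes had 0 higher and 12 lower responses of 62 (0 higher and 23 lower adjusted over the list alone). For the ribosomal protein genes camera adjusted p = 2.4e-16, or adjusted p = 0.123 with an estimated correlation. Histone genes had 0 higher and 1 lower responses of 15 (0 higher and 1 lower adjusted over the list alone). For the histone genes camera adjusted p = 0.0046, or adjusted p = 0.123 with an estimated correlation. Unfolded protein and ATF4 response genes had 4 higher and 9 lower responses of 35 (9 higher and 11 lower adjusted over the list alone). For unfolded protein genes camera adjusted p = 0.0037, or adjusted p = 0.395 with an estimated correlation. Cholesterol genes had 1 higher and 2 lower responses of 25 (1 higher and 6 lower adjusted over the list alone). For cholesterol biosynthesis genes camera adjusted p = 0.0029, or adjusted p = 0.417 with an estimated correlation. Heat shock genes had 0 higher and 1 lower responses of 22 (0 higher and 1 lower adjusted over the list alone). For heat shock and chaperone genes camera adjusted p = 0.0062, or adjusted p = 0.527 with an estimated correlation. This call was lost without SK-UT-1 control replicate 2 (0.072). YAP/TAZ targets, not called (camera adjusted p = 0.098), were called without SK-UT-1 control replicate 1 (0.048). HSP90AA1 had a difference of −0.75 ± 0.079 (limma adjusted p = 0.006). The difference of the seed-site shift was 0.015 (two-sided permutation test across genes, p = 0.0462). Among genes matched on UTR length, a test chosen after the result was seen, it was 0.002 (permutation test, p = 0.906). The shift itself in matched genes was −0.098 in SK-LMS-1 and −0.109 in SK-UT-1, so which line had the larger shift depended on the setting.

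The count of 1315 was sensitive to single libraries, and with replicate number as a block within each line it was 147. It was 264 without SK-LMS-1 control replicate 1, 319 without control replicate 2, and 416 and 261 without SK-LMS-1 mimic replicates 1 and 2. Without SK-UT-1 control replicates 1 and 2 it was 518 and 679, and without either SK-UT-1 mimic replicate 269. The TNS1 difference (1.66, limma adjusted p = 0.026) was lost when any 1 library other than SK-LMS-1 control replicate 1 was left out, with adjusted p up to 0.0864, and in recovered reads (0.94, limma adjusted p = 0.088). That of FXYD6 (limma adjusted p = 0.015) was lost without SK-LMS-1 mimic replicate 2 or either SK-UT-1 mimic replicate, with adjusted p up to 0.0622. Differences of single genes beyond the 5 largest of each direction were not refitted without single libraries.

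The control libraries set the background on which the mimic acted, and the lines differ widely. ALDH1A1, a retinaldehyde dehydrogenase, was at 1.34 ± 0.668 TPM in SK-LMS-1 and 1774 ± 62.2 in SK-UT-1 (log2 9.60 ± 0.20, limma adjusted p = 4.7e-08). QPCT, a glutaminyl cyclase, was at 0.668 ± 0.299 TPM in SK-LMS-1 and 199.8 ± 4.96 in SK-UT-1, and IL13RA2, an interleukin-13 receptor, at 2.94 ± 0.0258 TPM in SK-LMS-1 and 469.5 ± 22.2 in SK-UT-1. PRAC1 (7.42) and MT1A (7.46) were also higher in SK-UT-1, MT1A with the caution that metallothionein genes are near-identical. NNMT, nicotinamide N-methyltransferase, was at 474 ± 11.7 TPM in SK-LMS-1 and 0.268 ± 0.113 in SK-UT-1. UBB, 1 of the ubiquitin genes, was at 961 ± 35.5 TPM in SK-LMS-1 and 1.19 ± 0.318 in SK-UT-1 (log2 −8.79 ± 0.13), where polyubiquitin copies make the assignment of reads uncertain. SPANXA2 (−10.92), SPANXB1 (−8.72) and SPANXD (−8.46), cancer-testis genes near-identical to each other, were lower in SK-UT-1.

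In all, 11132 genes differed between the control lines, 6138 higher and 4994 lower in SK-UT-1, and 11365 had an unadjusted p under 0.05. SK-UT-1 had lower levels of extracellular matrix and collagen genes (3 higher and 35 lower of 41, 3 higher and 35 lower adjusted over the list alone, camera adjusted p = 1.9e-10, adjusted p = 0.152 with an estimated correlation). Epithelial-mesenchymal transition genes (6 higher and 19 lower of 25, 6 higher and 19 lower adjusted over the list alone, camera adjusted p = 5.2e-04, adjusted p = 0.203 with an estimated correlation) and YAP/TAZ targets (2 higher and 18 lower of 24, 2 higher and 18 lower adjusted over the list alone, camera adjusted p = 1.6e-04, adjusted p = 0.275 with an estimated correlation) were also lower. It had higher levels of interferon-stimulated genes (34 higher and 7 lower of 49, 34 higher and 7 lower adjusted over the list alone, camera adjusted p = 6.3e-04, adjusted p = 0.275 with an estimated correlation) and of mitosis genes (44 higher and 4 lower of 51, 44 higher and 4 lower adjusted over the list alone, camera adjusted p = 3.8e-07, adjusted p = 0.276 with an estimated correlation). G1/S genes (38 higher and 4 lower of 50, 38 higher and 5 lower adjusted over the list alone, camera adjusted p = 1.7e-04, adjusted p = 0.463 with an estimated correlation) and oxidative phosphorylation genes (39 higher and 6 lower of 47, 39 higher and 6 lower adjusted over the list alone, camera adjusted p = 1.6e-04, adjusted p = 0.275 with an estimated correlation) were higher too. So were the MYC list (31 higher and 3 lower of 37, 31 higher and 3 lower adjusted over the list alone, camera adjusted p = 2.3e-04, adjusted p = 0.478 with an estimated correlation), heat shock genes (17 higher and 5 lower of 22, 17 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.715 with an estimated correlation) and splicing factors (16 higher and 3 lower of 25, 18 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.382 with an estimated correlation). Cholesterol genes were lower (6 higher and 14 lower of 25, 6 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.664 with an estimated correlation). The heat shock call was lost without SK-LMS-1 control replicate 1 (0.057) or 2 (0.055), and the cholesterol call without SK-LMS-1 control replicate 2 (0.055) or SK-UT-1 control replicate 1 (0.06).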

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

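The results in this part are differences of the mimic's effect between the lines, SK-UT-1 minus SK-LMS-1, each past a test of the difference itself; of the tests here, the sum of SMIM11A and SMIM11B, those on recovered reads and that of the seed-site difference among matched genes were chosen after the result was seen. Values of genes are log2, and values of lists are the median difference of the members minus the median of all genes.

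Over all genes, 1315 had a difference past a limma adjusted p of 0.05. That count was 147 with replicate number as a block within each line, and it was also lower whenever a single library was left out. SMIM11A (2.64) and SMIM11B (−2.78) led each direction, and as near-identical copies they summed to 24.4 ± 2.17 TPM in control and 25.1 ± 1.80 TPM in mimic libraries of SK-LMS-1 and to 17.9 ± 1.34 and 20.9 ± 0.767 TPM in SK-UT-1. FXYD6 (1.89) and MYBPH (−1.88) were near 0 TPM in SK-LMS-1, and SERPINB4 (−1.94) and LRATD1 (−1.76) were near 0 TPM in SK-UT-1, and in recovered reads the calls of FXYD6 (1.07, limma adjusted p = 0.465), SERPINB4 (−2.80, limma adjusted p = 0.15) and LRATD1 (−1.36, limma adjusted p = 0.405) were lost, though the values kept their signs. TAGLN (1.84) rose in both lines and more in SK-UT-1. TNS1, the focal adhesion protein tensin-1, differed by 1.66 in TPM but by 0.94 in recovered reads, where the call was lost (limma adjusted p = 0.088) and SK-UT-1 showed no rise (0.004). IFIT2 (1.65) fell in SK-LMS-1 and RGS2 (−2.001) changed in opposite directions.

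Of the lists, G1/S and DNA replication genes had a difference of 0.34, G2/M and mitosis genes of 0.20, interferon-stimulated genes of 0.13 and smooth muscle contractile genes of 0.20, all higher in SK-UT-1. Lower responses were measured for NF-kB and inflammatory cytokine genes (−0.24), immediate early genes (−0.24), cytosolic ribosomal protein genes (−0.24), glycolysis and hypoxia genes (−0.38), cholesterol biosynthesis genes (−0.20), unfolded protein and ATF4 response genes (−0.17), heat shock and chaperone genes (−0.17) and replication-dependent histone genes (−0.37). None of the 12 was called with an estimated correlation in camera, where 8 of the 32 lists had an unadjusted p under 0.05, and fry called 16. The seed-site shift was smaller by 0.015 in SK-UT-1 without adjustment, but among genes matched on UTR length the difference was 0.002 (permutation test, p = 0.906). In those genes the shift was −0.098 in SK-LMS-1 and −0.109 in SK-UT-1, the larger one now in SK-UT-1.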

How the results depend on the processing

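Tests on recovered reads, without mitochondrial mRNA, with centring, of the seed-site difference between lines among genes matched on UTR length and without genes holding the words of the rises were chosen after the results were seen. The count of genes over both lines stayed within 1.5 times its value in every setting that kept the threshold, from 3906 to 7183, as did that between control lines among genes, from 9252 to 11904. With only the 4 libraries of the line, SK-UT-1 had 2910 calls, where fewer degrees of freedom remain. Tested as 61254 transcripts, 1958 changed in SK-LMS-1, 2647 in SK-UT-1, 18 between responses and 21513 between control lines; the unit tested differs. Requiring 2-fold left 272, 306, 176 over both lines, 219 between responses, 4335 between control lines, and 5 literature targets lower in each line. An adjusted p under 0.01 left 1705 in SK-LMS-1, 2297 in SK-UT-1, 3227 over both lines and 153 between responses. Voom on recovered reads called more: 6139 in SK-LMS-1, 6992 in SK-UT-1 and 3173 between responses; the cause was not tested. Of the SK-LMS-1 calls, 3352 of 3642 genes tested both ways were called in the same direction there, and 4219 of 4543 in SK-UT-1.

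Leaving out 1 library gave 2039 to 2269 calls in SK-LMS-1, 2718 to 3337 in SK-UT-1 and 261 to 679 between responses, fits with 1 library in an arm and fewer degrees of freedom. For lists, an estimated correlation left 0 in SK-LMS-1 and 0 in SK-UT-1 (camera, with 1 and 5 lists at an unadjusted p under 0.05), and fry called 12 in SK-LMS-1; the cause was not tested. The seed-site shift kept its sign in every setting but one: with 6-mer matches alone it was 0.0015 in SK-LMS-1 and 0.034 in SK-UT-1 (permutation test, p = 0.786 and 6e-05); the cause was not tested. The difference of the shift between the lines (0.015) was 0.0021 among genes matched on UTR length (permutation test, p = 0.906); the cause was not tested. Without single libraries the shift ran from −0.084 to −0.073 and from −0.076 to −0.059. The 318 results for single genes include genes that were not called. Leaving out a library left the result as it was, called or not called, in 1160 of 1312 fits and lost a call in 152. Other alternatives left 3023 of 3160 as they were, lost 119 calls and gained 17. They turned 1 in sign, NDUFA6 in SK-UT-1 (0.58), in recovered reads, where the cause was not tested. The unchanged results are therefore not a count of kept calls.

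Replicate numbers are shared between groups, but nothing says that they pair samples, and deviations of same-numbered libraries correlated at 0.053 in SK-LMS-1 and 0.013 in SK-UT-1. With replicate number as a block within each line, 2818 genes were called in SK-LMS-1, 3827 in SK-UT-1, 4857 over both lines, 147 between responses and 11001 between control lines, and the lists called stayed at 7 and 12. Of these counts, that between responses moved by more than 1.5 times.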

Other observations

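All tests of words other than the seed of miR-10b-5p, beyond their rank, were chosen only after the result was seen; the tests that decide each explanation were written down before. Besides RGS2, 3 named genes were called in opposite directions in the lines. NDRG1, a hypoxia-induced gene, rose in SK-LMS-1 (0.84 ± 0.10) and fell in SK-UT-1 (−0.71 ± 0.10; difference limma adjusted p = 0.0047). TUBB3, a neuronal tubulin, rose from 40.8 ± 1.97 to 66.3 ± 3.75 TPM in SK-LMS-1 and fell from 295 ± 7.68 to 229 ± 2.94 TPM in SK-UT-1 (difference −1.06 ± 0.077). IL13RA2 rose from 2.94 ± 0.0258 to 6.51 ± 0.110 TPM in SK-LMS-1 and fell from 469.5 ± 22.2 to 340.4 ± 8.84 TPM in SK-UT-1 (difference −1.39 ± 0.073). In SK-UT-1 the chemokine genes CXCL1 (−1.14), CXCL3 (−1.66) and CXCL8 (−1.201) fell. In SK-LMS-1 CXCL8 fell (−1.29), and CXCL1 passed in recovered reads (−0.69, limma adjusted p = 0.0014), a test chosen after the result was seen.

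For the genes changed over both lines, the 8 libraries can be split into 2 sets of 4 in 35 ways, of which 34 could be fitted in a model with the line and the split as terms. The real split called 3906 genes, the highest of the others 2, and 1 of the 34, the real one, gave as many. Only splits that take 2 libraries of each line are shaped like the real one, and the others count in the share too. All splits but the real one also leave any mimic effect in the residual spread, which lowers their counts. The real split called by far the most genes, but for these reasons the share of splits cannot exclude a random grouping. Anything else shared by all mimic libraries cannot be told apart from the mimic.

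Genes with miR-10b-5p sites were lower than other genes after the mimic in both lines, and 31.0% of the genes that fell in SK-LMS-1 and 31.3% in SK-UT-1 held a 7-mer or 8-mer, against 14.0% and 14.5% of those that rose, 17.6% and 18.6% of those not past the test and 19.04% of all genes. If 3′ UTR length or base composition were the cause, the seed word should have been unremarkable with both in the fit, but its rank was 1 among all 7-mers in each line, and genes matched on UTR length differed by −0.098 and −0.109. Repression by the transfected microRNA is a candidate explanation for part of the falls, as a hypothesis. Most genes that fell hold no such site in the longest annotated 3′ UTR, and whether they follow from the targets, from sites elsewhere or from something else was not tested.

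Rises in both lines went with 2 words in the 3′ UTR that do not match miR-10b-5p. GACAGTA (t = 11.9) and TGACGTA (9.81) ranked 1 and 2 in SK-LMS-1, and TGACGTA (7.88) and GACAGTA (7.51) in SK-UT-1, above the highest t of 100 shufflings of the fold changes over genes (5.61 and 4.77). For counting, TGACGTA was shortened to GACGTA, which other 7-mers also hold, so genes holding the words are those with GACAGTA or GACGTA. These made up 12.3% of genes, but 52.3% of the genes that rose 2-fold in SK-LMS-1 (57 of 109) and 35.7% in SK-UT-1 (50 of 140), among them MET, PTPMT1, BANF1 and H3-3A. The words were picked by their slopes on these same fold changes, so the shares restate that choice and add no separate support. Relief of a repression by seed matches of the control mimic in the control libraries may account for such rises; the bound set for it, a shared run of 6 bases between the top words of the lines, was not met (3 bases), which by the rule written before counts against it. That rule compared only the words of rank 1, while the same pair holds ranks 1 and 2 in swapped order, so the matter is left open. Without untransfected libraries, that relief and a rise caused by the miR-10b-5p mimic cannot be told apart, the control mimic's sequence is not given in the sources used here, and without genes holding the words 2994 genes were called in SK-LMS-1 (1273 higher, against 1737 with them) and 3900 in SK-UT-1 (2546 higher, against 3105), so most rises are of genes without the words.

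Because the values are sums of transcript abundances, a switch between isoforms of different length could change a gene's TPM without a change in its reads. Over called genes with a change of at least 2-fold that were also tested in reads, the median ratio of the log2 change in recovered reads to that in TPM was 1.102 in SK-LMS-1 (260 of 272 genes) and 1.12 in SK-UT-1 (274 of 306 genes), where reads moved between isoforms would give a ratio under 0.5, and 4 and 5 genes had one. In reads, 246 and 261 of these genes were called in the same direction. The large changes as a set are thus not mainly the product of such moves. Changes of TPM + 1 are understated for genes of low level, which raises the ratio, so a smaller contribution is not excluded. For single genes of small change, such as NDUFA6 in SK-UT-1, the matter stays open.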
